A study of Mus musculus with 12 samples.

How the data were processed

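Expression was measured in whole heart and whole gastrocnemius of mice carrying the C26 tumour, a colon carcinoma line used as a model of cancer cachexia, and of non-tumour-bearing (NTB) mice injected with culture medium alone. The tumour cells were placed under the skin of the flank, and the mice were Balb/c-DBAj hybrids, per the labels. The labels put 3 biological replicates in each of the 4 groups, so that 12 arrays were compared. Hearts and gastrocnemius muscles came from separate cohorts, per the labels' protocols, and no animal is stated to have given both. Tissue was snap-frozen, total RNA was extracted with TRIzol, and 250 ng per sample was turned into biotin-labelled cDNA with the Ambion WT kit, per the labels' protocols. Each sample was hybridised to a 1-colour Affymetrix array, MoGene-1_0-st-v1.

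The deposited values that were used are log2 expression values, 1 per row and array, made by the authors with RMA (robust multi-array average, which corrects background, normalizes the probes between arrays and summarises them per transcript). RMA, GCOS and Partek and the genome build mm8 are named without versions or roles, per the submitters' processing notes. That the scale is log2 was read from the range of the values. No centring of genes was seen, as the levels kept the spread of RMA values. Whether all 12 arrays were normalized together is not stated. The column medians over all measured transcripts were 6.06, 6.07 and 6.04 in C26 hearts 1 to 3, 6.06, 6.04 and 6.05 in NTB hearts 1 to 3, 5.93, 5.98 and 6.09 in C26 gastrocnemius 1 to 3, and 5.98, 5.96 and 6.01 in NTB gastrocnemius 1 to 3. A second deposited table was used only for the gene names. Its 12 columns of per-sample values were not used, because their names were not those of the samples. The names carry codes that are not explained and were not assigned to arrays, so whether they mark batches was not tested. The plan had put that table first if it held log2 values per sample, and the series' own value table was used instead.

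The table held 35556 transcripts, of which 23819 had a gene symbol and 11737 had none. The gene symbols and transcript accessions of the deposited table stop after 7 characters. A symbol of 7 characters was therefore named only where a single gene of the mouse gene table of assembly GRCm38.p6 fitted the start of the symbol, together with the start of the accession where this was given. Of 7122 such transcripts, 5059 were named and 2063 were left unnamed. Of 16697 shorter symbols, 16571 were in that table, 883 of them under an older name. In all, 21756 transcripts were named, and 215 of them had an accession start that differs from that of the gene in the table. They stood for 19327 genes, 1347 of them with more than 1 transcript on the array, and the transcript with the highest mean over the 12 arrays was kept for each gene.

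The tests were run in R 4.3.3 with limma 3.58.1. One linear model with 4 group means was fitted to the log2 values of all 12 arrays, with variances moderated along the trend with expression (8 residual and a median of 6.8 prior degrees of freedom). The contrasts were C26 minus NTB in gastrocnemius, C26 minus NTB in heart, the difference of these effects (gastrocnemius minus heart), and NTB heart minus NTB gastrocnemius. Tests were two-sided, p values were adjusted by Benjamini and Hochberg over the 19327 genes, and "rose", "fell" and "called" refer to an adjusted p under 0.05. No filter on dim transcripts was applied. Each change is a difference of log2 means of 3 arrays against 3, for leading genes with its standard error (SE) from the fit.

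Gene lists were tested with camera, the competitive test of limma, at its preset correlation between genes of 0.01, adjusted over the 41 lists tested within each comparison. Of 42 lists that were fixed, the list of sex-specific genes had too few measured members and was not tested. Camera with a correlation estimated from the arrays, and fry, were alternatives. With the estimated correlation 0 of the 41 lists were called in any comparison, against 29, 26 and 20 for gastrocnemius, heart and the difference with the preset value. Fry, which asks whether the genes of a list move on balance in one direction, called 26, 10 and 8 lists. For each list the members that rose or fell over all genes are counted beside the count adjusted over the list alone, for the difference only as a maximum where the list was not called.

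The comparisons, the gene lists, all alternatives but 1 and the rule for the genes named were fixed before the data were examined. The rule took the 10 largest rises and the 10 largest falls of each tumour comparison among called genes whose 3 C26 arrays all lay on one side of the 3 NTB arrays, and the 5 largest in each direction for the difference of effects and for the muscles of NTB mice, leaving out predicted genes. It also took Trim63, Fbxo32, Foxo1, Socs3, Myh1, Myh2, Myh4, Myh6, Myh7, Nppa, Nppb, Acta1 and Mstn, up to 4 members with the smallest p of each list and comparison, and any gene raised later by set rules for outliers and for group differences. Among these, examples were preferably taken where the call held in every alternative. Where 5 or fewer members of a list changed, all are named, and those beyond the rule were chosen after their values were seen, as were the genes called in opposite directions in the muscles.

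The alternatives were quantile normalization over all arrays or within each muscle, subtraction of each array's median, leaving out the dimmest 1 of every 3 genes, the mean of all transcripts of a gene, every transcript tested on its own, no trend, no moderation, array weights, the arrays of the compared groups alone, the replicate number as a block, and leaving out each of the 12 arrays in turn. One more, without both gastrocnemius arrays numbered 3, was added after the data were seen. The groups share the replicate numbers 1 to 3, and whether these pair the samples was checked from the correlation, across genes, of the deviations from the group means (genes are not independent replicates). In gastrocnemius C26 and NTB arrays of the same number had r = 0.31, 0.33 and 0.50, over the set limit of 0.1. Different numbers had -0.44 to 0.13. Deviations sum to 0 in each group, so high same-number values lower the others and do not establish pairs, which the labels do not give. In heart the values were 0.09, -0.04 and 0.02, under the limit.

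Within groups, arrays correlated across genes with r between 0.968 and 0.991 in gastrocnemius and between 0.993 and 0.995 in heart. The median standard deviation of a gene was 0.161 in NTB gastrocnemius, 0.213 in C26 gastrocnemius, 0.112 in NTB heart and 0.109 in C26 heart on the log2 scale. The smallest mean absolute difference between 2 arrays was 0.188, between C26 hearts 2 and 3. On arrays simulated from the gene means and the residual spread of the fit, with 19327 genes, changes of 0.5, 1 and 2 on the log2 scale were called in 16.4% of 73, 81.7% of 71 and 96.4% of 56 changed genes, with 6 false calls. Camera recovered proteasome subunits moved by 0.3 in a simulated heart comparison (adjusted p = 1.02e-17) and called 0 of the other lists. Correlation between genes (estimated at 0.427 for this list) was not simulated, so this does not vouch for the real list calls. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.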

Results

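Expression was compared between mice carrying the C26 colon carcinoma, whose tumour brings on cachexia (the wasting of muscle and fat in cancer), and non-tumour-bearing (NTB) mice injected with medium alone. Whole gastrocnemius, a limb muscle, and whole heart were measured on 3 arrays per group, 12 arrays in all, and 19327 genes were tested. In C26 gastrocnemius 1233 genes rose and 1049 fell, which together is 11.81% of the genes, and in C26 heart 414 rose and 214 fell (3.25%). With the arrays of each muscle fitted alone 894 genes were called in gastrocnemius and 2212 in heart, so that the order of the muscles was reversed. All changes below are C26 minus NTB differences of mean log2 values (n = 3 arrays per group) with the standard error of the fit after ±, and adjusted p values of genes are from limma. The muscles came from separate cohorts, so a difference between muscles is also a difference between cohorts.

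The ubiquitin ligase, proteasome and autophagy lists were called higher in C26 gastrocnemius. Trim63 (MuRF1) and Fbxo32 (atrogin-1), the ubiquitin ligases by which muscle atrophy is usually followed, rose 5.78-fold (log2 2.53 ± 0.18, adjusted p = 3.85e-07) and 5.01-fold (log2 2.33 ± 0.13, adjusted p = 7.56e-08). Fbxo31 rose by 1.28 ± 0.13 and the ubiquitin gene Ubb by 0.59 ± 0.09. The proteasome had 25 of 37 subunit genes up and 0 down (28 and 0 adjusted over the list alone), with Psma7 at 1.59, Psmd4 at 1.32 and Psmd2 at 1.02, and the list median was 0.62 (camera adjusted p = 4.29e-18, adjusted p = 0.218 with an estimated correlation). Of 22 genes of the ubiquitin ligases of atrophy 9 rose and 0 fell (10 and 1 adjusted over the list alone), and 1 fell without C26 gastrocnemius array 1 or NTB gastrocnemius array 2 or with the replicate number as a block. The median was 0.27 (adjusted p = 2.83e-05, adjusted p = 0.218 with an estimated correlation), and 0.18 without C26 gastrocnemius array 1. Of 40 autophagy and lysosome genes 13 rose (17 adjusted over the list alone), with the lysosomal protease Ctsl at 1.79 and the autophagosome genes Gabarapl1 at 1.60 and Map1lc3b at 1.30. The median was 0.16 (adjusted p = 5.40e-06, adjusted p = 0.292 with an estimated correlation). The 2 that fell (3 adjusted over the list alone) were Ulk2 (-0.41) and Fundc1 (-0.50), and both calls were lost in most fits without 1 array (adjusted p up to 0.161). The median of the autophagy list was 0.30, 0.26 and 0.09 without C26 gastrocnemius array 3, NTB gastrocnemius array 2 and C26 gastrocnemius array 1.

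Genes induced by glucocorticoids and FoxO factors, which act upstream of these ligases, were called higher as a list in C26 gastrocnemius. Of 30 genes 19 rose and 2 fell (21 and 2 adjusted over the list alone), with a median of 0.92 (camera adjusted p = 7.32e-15, adjusted p = 0.115 with an estimated correlation). The metallothioneins Mt1 and Mt2, which bind zinc and copper, rose by 3.25 ± 0.13 (9.49-fold, adjusted p = 2.20e-09) and 4.06 ± 0.30 (16.7-fold, adjusted p = 6.74e-07). The translation inhibitor Eif4ebp1 rose by 1.98 ± 0.14, the mTORC1 inhibitor Sesn1 by 1.76 and Gadd45a by 1.58. Foxo1 itself rose by 0.76 ± 0.21 (adjusted p = 0.0262), a call lost without C26 gastrocnemius array 2 or NTB gastrocnemius array 3 (adjusted p up to 0.134). The 2 genes that fell were Sesn3 (-0.75) and Dusp1 (-0.82), the latter not called without NTB gastrocnemius array 2 (adjusted p = 0.0550). The largest rises also held the chemokine Cxcl13 (3.25), the scaffold gene Cnksr1 (2.62), Bex1 (2.49) and the stretch-responsive Ankrd1 (2.36).

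**Figure D1:**
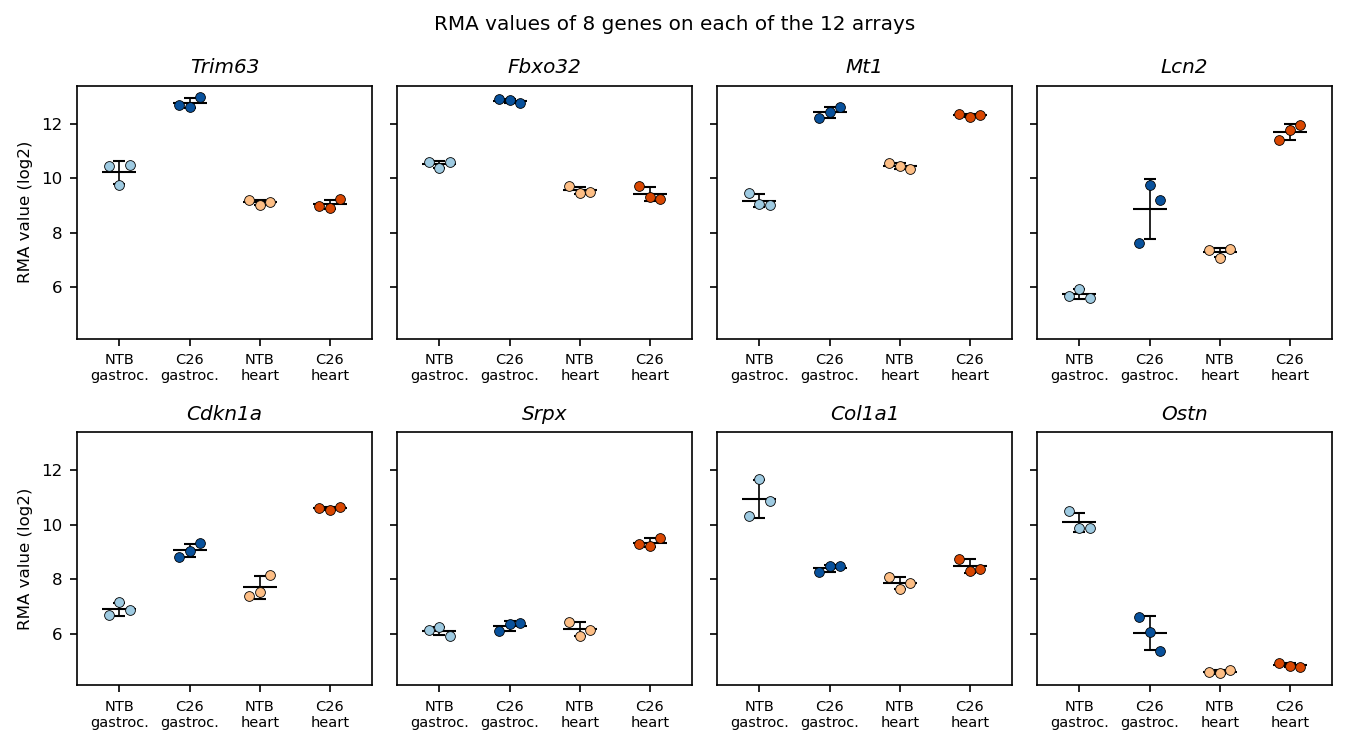
RMA values (log2) of 8 genes on each of the 12 arrays (points), by muscle and tumour state, with the group mean (line) and SD (bars). Trim63 and Fbxo32 are higher in all 3 C26 gastrocnemius arrays than in all NTB ones, while C26 and NTB hearts overlap.

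The oxidative phosphorylation and tricarboxylic acid cycle lists were called lower in C26 gastrocnemius. Of 76 subunit genes of oxidative phosphorylation 37 fell and 0 rose (65 and 0 adjusted over the list alone), among them Ndufs1 (-0.88) and Sdhd (-0.94), with a median of -0.57 (camera adjusted p = 4.91e-26, adjusted p = 0.218 with an estimated correlation). The median was -0.35 without C26 gastrocnemius array 3, in which these genes lay at -0.58 against the other arrays of its group. The count was 57 without C26 gastrocnemius array 1 and 61 with the block. Of 26 genes of the tricarboxylic acid cycle 18 fell and 0 rose (21 and 0 adjusted over the list alone), with Idh3a at -0.94 and Dlat at -0.97. The median was -0.55 (adjusted p = 4.41e-14, adjusted p = 0.218 with an estimated correlation). Of 34 genes of glycogen and glycolysis 15 fell and 3 rose (17 and 5 adjusted over the list alone). The median was -0.40 (adjusted p = 9.42e-05, adjusted p = 0.292 with an estimated correlation), and -0.23 without C26 gastrocnemius array 3. Pgm2 fell by 1.95 ± 0.19, the phosphorylase kinase subunit Phka1 by 1.58 and Pkm by 0.97, whereas the glycogen synthesis genes Ugp2 (1.47), Gbe1 (0.67) and Gyg (0.60) rose. Gyg was not called without C26 gastrocnemius array 2 (adjusted p = 0.0560), and 5 genes rose without C26 gastrocnemius array 3. Genes of fatty acid uptake and oxidation moved the other way, with 14 of 41 up and 3 down (17 and 6 adjusted over the list alone). The median was 0.25 (adjusted p = 1.12e-04, adjusted p = 0.401 with an estimated correlation), and 0.16 and 0.41 without C26 gastrocnemius arrays 1 and 3. The lipase Pnpla2 rose by 1.12 ± 0.12, the transporter Cd36 by 0.89 and Acadl by 0.85. Acaa2 (-0.81), Esrra (-0.60) and Ppargc1b (-0.71) fell, of which Esrra was lost without NTB gastrocnemius array 1 and Ppargc1b without NTB gastrocnemius array 2 (adjusted p up to 0.0573), and 7 fell without C26 gastrocnemius array 1 or with the block.

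The acute phase, interleukin-6 and NF-kappa B lists were called higher in C26 gastrocnemius. Lcn2 (lipocalin 2, an iron-binding acute phase protein) rose 8.64-fold (log2 3.11 ± 0.36, adjusted p = 3.94e-05) and haptoglobin (Hp) 7.64-fold (log2 2.93 ± 0.36). Of 25 acute phase genes 10 rose and 0 fell (10 and 0 adjusted over the list alone). The median was 0.35 (adjusted p = 1.99e-06, adjusted p = 0.218 with an estimated correlation), and 0.22 without C26 gastrocnemius array 3. Of 28 genes of the interleukin-6 and STAT3 pathway 10 rose and 2 fell (11 and 3 adjusted over the list alone), with the oncostatin M receptor Osmr at 1.90, Il6ra at 1.75, Stat3 at 1.27 and Socs3 at 0.98. The median was 0.32 (adjusted p = 3.13e-04, adjusted p = 0.221 with an estimated correlation), and 0.15 and 0.19 without C26 gastrocnemius array 2 and NTB gastrocnemius array 3. Lifr (-0.65) and Bcl6 (-1.41) fell, Bcl6 not without NTB gastrocnemius array 2 or 3 (adjusted p up to 0.0699). Of 29 NF-kappa B targets 7 rose and only Sod2 (-0.56) fell (8 and 2 adjusted over the list alone), and 2 fell without C26 gastrocnemius array 1, without NTB gastrocnemius array 3, or with the block. The median was 0.18 (adjusted p = 0.0022, adjusted p = 0.218 with an estimated correlation), and 0.08 without NTB gastrocnemius array 2. The interferon response list was not called (median -0.02, adjusted p = 0.304). In it 0 genes rose and 1, Gbp6 (-0.79), fell (0 and 1 adjusted over the list alone), and 3, 4 and 2 genes fell without C26 gastrocnemius array 1, C26 gastrocnemius array 3 and NTB gastrocnemius array 3. With the block 1 rose and 2 fell, and 1 rose without C26 heart array 3, C26 gastrocnemius array 3 or NTB gastrocnemius array 1.

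The ribosome and stress lists were called higher in C26 gastrocnemius as well. Of 41 ribosome biogenesis genes 22 rose and 0 fell (25 and 0 adjusted over the list alone), with Tsr1 at 1.48, Gnl3 at 1.45 and Nop14 at 1.36. The median was 0.57 (adjusted p = 5.73e-17, adjusted p = 0.218 with an estimated correlation). Of 52 cytosolic ribosomal protein genes 9 rose and 0 fell (12 and 0 adjusted over the list alone). The median was 0.26 (adjusted p = 4.08e-09, adjusted p = 0.218 with an estimated correlation). That count was 5 without NTB heart array 1, C26 gastrocnemius array 2 or NTB gastrocnemius array 2, and 19 without C26 gastrocnemius array 3 or with the block. Of 26 genes of oxidative stress and metal ions 11 rose and 3 fell (12 and 3 adjusted over the list alone). The median was 0.26 (adjusted p = 2.83e-05, adjusted p = 0.262 with an estimated correlation), and 0.42 without C26 gastrocnemius array 3. Besides the metallothioneins Gpx3 rose (1.54), and the transferrin receptor Tfrc (-3.06 ± 0.16, adjusted p = 5.64e-08), Sod2 and the zinc transporter Slc30a2 (-0.86) fell. Of 23 heat shock genes 9 rose and 2 fell (11 and 2 adjusted over the list alone), with Hspb7 at 1.49 and Hspb1 at 1.23 and falls of Hspb2 (-1.07) and Hspb3 (-0.75). The median was 0.28 (adjusted p = 3.20e-05, adjusted p = 0.380 with an estimated correlation), and 0.43 without C26 gastrocnemius array 3. Hspb3 was lost without NTB gastrocnemius array 1 or 3 (adjusted p up to 0.0867). Of 29 genes of the unfolded protein response 8 rose and 0 fell (9 and 0 adjusted over the list alone), with Edem1 at 1.04, and the count was 5 without C26 gastrocnemius array 2 or NTB gastrocnemius array 3 and 13 without C26 gastrocnemius array 3. The median was 0.24 (adjusted p = 3.56e-05, adjusted p = 0.224 with an estimated correlation). Of 34 ATF4 and amino acid stress genes 8 rose and 1 fell (11 and 1 adjusted over the list alone), with Slc3a2 at 1.07. The median was 0.21 (adjusted p = 5.08e-04, adjusted p = 0.218 with an estimated correlation), and 0.13 without C26 gastrocnemius array 1 or NTB gastrocnemius array 3. The fall was that of Psph (-0.54), lost without C26 gastrocnemius array 2 or NTB gastrocnemius array 1 (adjusted p up to 0.0713).

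The matrix list was called lower in C26 gastrocnemius. Col1a1 fell by 2.54 ± 0.25, Col1a2 by 2.21 ± 0.19, Col3a1 by 1.44 and fibromodulin (Fmod) by 1.99. Of 50 extracellular matrix genes 23 fell and 2 rose (25 and 2 adjusted over the list alone). The median was -0.38 (adjusted p = 1.90e-10, adjusted p = 0.262 with an estimated correlation). The collagen crosslinking enzyme Lox (1.16) and Fbln1 (0.68) rose, and 4 rose without C26 gastrocnemius array 3. Among fibroblast markers 6 of 20 fell and 1 rose (9 and 1 adjusted over the list alone). The median was -0.21 (adjusted p = 1.16e-04, adjusted p = 0.277 with an estimated correlation). The rise of Ly6a (0.71) was lost without C26 gastrocnemius array 1 or 2 or NTB gastrocnemius array 1 or 3 (adjusted p up to 0.141). Matrix proteases and their inhibitors were not called as a list (median 0.09, adjusted p = 0.754). Of 23, Mmp3 (1.58), Adamts9 (0.64) and Mmp14 (0.69) rose, and Mmp15 (-0.69), Adamts5 (-0.66), Timp2 (-0.59) and Timp3 (-0.41) fell (3 and 4 adjusted over the list alone). Except for Mmp3 each of these calls was lost without 1 or more arrays (adjusted p up to 0.163). Without NTB gastrocnemius array 2, 0 fell, and without C26 gastrocnemius array 2 or NTB gastrocnemius array 3, 1 rose. In the TGF-beta, activin and myostatin pathway 6 of 34 fell and 3 rose (6 and 3 adjusted over the list alone), with Gdf11 at -0.91 and Tgfbr2 at 0.69. The median was -0.12 (adjusted p = 0.0379, adjusted p = 0.464 with an estimated correlation). That list was not called without C26 gastrocnemius array 3 (adjusted p = 0.302) or NTB gastrocnemius array 2, and its median was -0.21 without NTB gastrocnemius array 3. Mstn (myostatin) was not called (-0.32, adjusted p = 0.254).

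Myosin heavy chain genes, which set the contraction speed of a fibre, were not called in C26 gastrocnemius. The log2 changes were -0.03 for Myh1 (adjusted p = 0.964), -0.46 for Myh2 (0.0812), -0.16 for Myh4 (0.750), -0.13 for Myh6 and -0.13 for Myh7, and Myh2 was called with quantile normalization. Of 20 fast fibre genes 8 fell and 1 rose (9 and 1 adjusted over the list alone). The median was -0.22 (adjusted p = 1.97e-05, adjusted p = 0.218 with an estimated correlation). Casq1, the calcium store protein of the sarcoplasmic reticulum, fell by 2.40 ± 0.20, Cacna1s by 0.92 and parvalbumin (Pvalb) by 0.97, and the rise of Mylk2 (0.62) was lost without C26 gastrocnemius array 2 or NTB gastrocnemius array 3 (adjusted p up to 0.0569). Slow fibre genes were not called as a list (median -0.13, adjusted p = 0.519). Of 15, Csrp3 (1.79), Ankrd2 (1.60) and Myoz2 (0.52) rose and Mb (-0.93) and Myl3 (-1.23) fell (3 and 2 adjusted over the list alone). Myoz2 and Myl3 were lost without several arrays, C26 gastrocnemius array 2 among them (adjusted p up to 0.155), and without C26 gastrocnemius array 1 the list was called lower (adjusted p = 0.0143) and 5 fell. Of 33 cardiac contraction and calcium genes 3 fell, Actc1 (-3.06), Popdc2 (-1.08) and Myl3 (3 adjusted over the list alone). The median was -0.13 (adjusted p = 0.0081, adjusted p = 0.260 with an estimated correlation). Cardiac stress and fetal genes had 7 of 20 up and 2 down (7 and 2 adjusted over the list alone). The median was 0.04 (adjusted p = 0.0139, adjusted p = 0.401 with an estimated correlation). Ccn2 (-0.71) and Xirp2 (-0.45) fell, Xirp2 not in most fits without 1 array (adjusted p up to 0.144), and the list was not called without C26 gastrocnemius array 1 (adjusted p = 0.108). Its median was 0.00, 0.08 and 0.02 without C26 gastrocnemius arrays 1 to 3, and 0.08, 0.02 and -0.04 without NTB gastrocnemius arrays 1 to 3. Nppa (0.11), Nppb (0.15) and Acta1 (-0.15) were not called. Atrial genes were not called (median -0.20, adjusted p = 0.128), with Clu (0.63) up and Myl1 (-1.14) and Dkk3 (-0.58) down of 11 (1 and 2 adjusted over the list alone), and Dkk3 was lost without C26 gastrocnemius array 2 (adjusted p = 0.0517). Of 25 genes of muscle regeneration and denervation 6 rose and 2 fell (7 and 2 adjusted over the list alone). The median was 0.04 (adjusted p = 0.0460, adjusted p = 0.380 with an estimated correlation). Myf6 rose by 0.91, and the acetylcholine receptor gene Chrne (-1.24) and Hdac9 (-0.81) fell. The list was not called without C26 gastrocnemius array 1 or 2 or NTB gastrocnemius array 3 (adjusted p up to 0.146), and its median was 0.02, 0.07 and 0.20 without C26 gastrocnemius arrays 1 to 3 and 0.14 and 0.01 without NTB gastrocnemius arrays 2 and 3.

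Clock and polyamine genes changed in both directions in C26 gastrocnemius. Of 19 clock genes 6 rose and 8 fell (7 and 8 adjusted over the list alone), so that the list was not called (median -0.33, adjusted p = 0.366). Arntl rose by 1.88 ± 0.16 and Rora by 1.20 ± 0.11, while Dbp fell by 2.72 ± 0.20 and Bhlhe41 by 1.70. Of 10 polyamine genes the spermine oxidase Smox (-2.51), Amd1 (-2.52), Oaz2 (-1.19), Oaz1 (-0.87) and Sms (-0.70) fell, and Sat1 (0.98), Srm (0.71) and Odc1 (0.66) rose (5 and 3 adjusted over the list alone). The median was -0.49 (adjusted p = 0.0141, adjusted p = 0.380 with an estimated correlation), and -0.32 without C26 gastrocnemius array 3. The list was not called without NTB gastrocnemius array 2 (adjusted p = 0.0594), Sms was lost without NTB gastrocnemius array 1 or 2 and Odc1 without NTB gastrocnemius array 3 (adjusted p up to 0.0670). Cell cycle genes were not called as a list (median -0.02, adjusted p = 0.535), with Aurka (-0.62), Ccnd1 (-0.63) and Mcm2 (-0.48) down of 30 (3 adjusted over the list alone). Mcm2 was lost without NTB gastrocnemius array 1 (adjusted p = 0.1003), and 1 gene rose without C26 gastrocnemius array 3. The largest falls were those of Ostn (osteocrin, a peptide secreted by muscle; -4.07 ± 0.24, adjusted p = 9.91e-08), Plcd4 (-3.09), Tfrc, Actc1, Nrep (-3.03), Slc37a4 (-2.98), Map2k6 (-2.93), Gdap1 (-2.80), Itgb6 (-2.80) and Igfbp5 (-2.74).

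Markers of other cell types gave the following values in C26 gastrocnemius. Of 20 endothelial markers 6 rose and 0 fell (8 and 1 adjusted over the list alone), with 2 called without NTB gastrocnemius array 1 and 3 without NTB gastrocnemius array 3. The median was 0.26 (adjusted p = 2.20e-04, adjusted p = 0.260 with an estimated correlation). The erythroid list was called higher, with Hba-a1 (1.28), Hba-a2 (1.26), Hbb-b1 (1.18) and Alas2 (1.21) up and Bpgm (-1.80) down of 12 (5 and 1 adjusted over the list alone). The median was 0.30 (adjusted p = 0.0022, adjusted p = 0.292 with an estimated correlation), and 0.18 without C26 gastrocnemius array 3. The adipocyte list was called higher, but not without C26 gastrocnemius array 3 (adjusted p = 0.421). Adipocyte markers had a median of 0.62 (adjusted p = 0.0172, adjusted p = 0.464 with an estimated correlation), and of 0.35 without that array. Of 18, Plin4 (0.97), Lipe (0.66), Pck1 (1.05), Cidea (0.99) and Fabp4 (0.89) rose, and Gpd1 (-2.02) and Scd1 (-1.34) fell (7 and 2 adjusted over the list alone). All but Plin4 and Gpd1 were lost without 1 or more arrays (adjusted p up to 0.224), and 10 rose without C26 gastrocnemius array 1. Macrophage markers had a median of 0.21 (adjusted p = 0.0187, adjusted p = 0.581 with an estimated correlation), with Cd68 (0.74) alone called of 20 (1 adjusted over the list alone), 3 with the block and 8 without C26 gastrocnemius array 1. That list was not called without C26 gastrocnemius array 2 or 3 or NTB gastrocnemius array 1 or 3 (adjusted p up to 0.541), and its median was 0.42, 0.12 and 0.08 without C26 gastrocnemius arrays 1, 2 and 3. Not called were the markers of neutrophils (median 0.04, adjusted p = 0.253; Lcn2 alone of 18 rose, 1 adjusted over the list alone), lymphocytes (0.22, 0.146), MHC class II (-0.06, 0.772), Schwann cells and nerve (median -0.02, mean 0.01, 0.915), smooth muscle (-0.07, 0.172; Smtn alone of 15 fell, by 0.71, 1 adjusted over the list alone) and epithelial tumour cells (-0.04, 0.639). In the lymphocyte, MHC class II, Schwann cell and epithelial lists 0 genes were called (0 adjusted over the list alone), and 0, 0, 0 and 2 had an unadjusted p under 0.05. Without C26 gastrocnemius array 1 the neutrophil (adjusted p = 0.0220), lymphocyte (0.0046, and 0.0045 without C26 gastrocnemius array 2) and smooth muscle lists (0.0389) were called. Without C26 gastrocnemius array 3 the MHC class II list was called lower (median -0.34, adjusted p = 0.0172), 1 of its genes fell, and 1 Schwann cell and 1 epithelial marker rose. With the block 1 Schwann cell marker rose and 1 endothelial marker fell. Of the smooth muscle markers 3 fell without C26 gastrocnemius array 1 or with the block, and 2 without NTB gastrocnemius array 3.

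**Figure D2:**
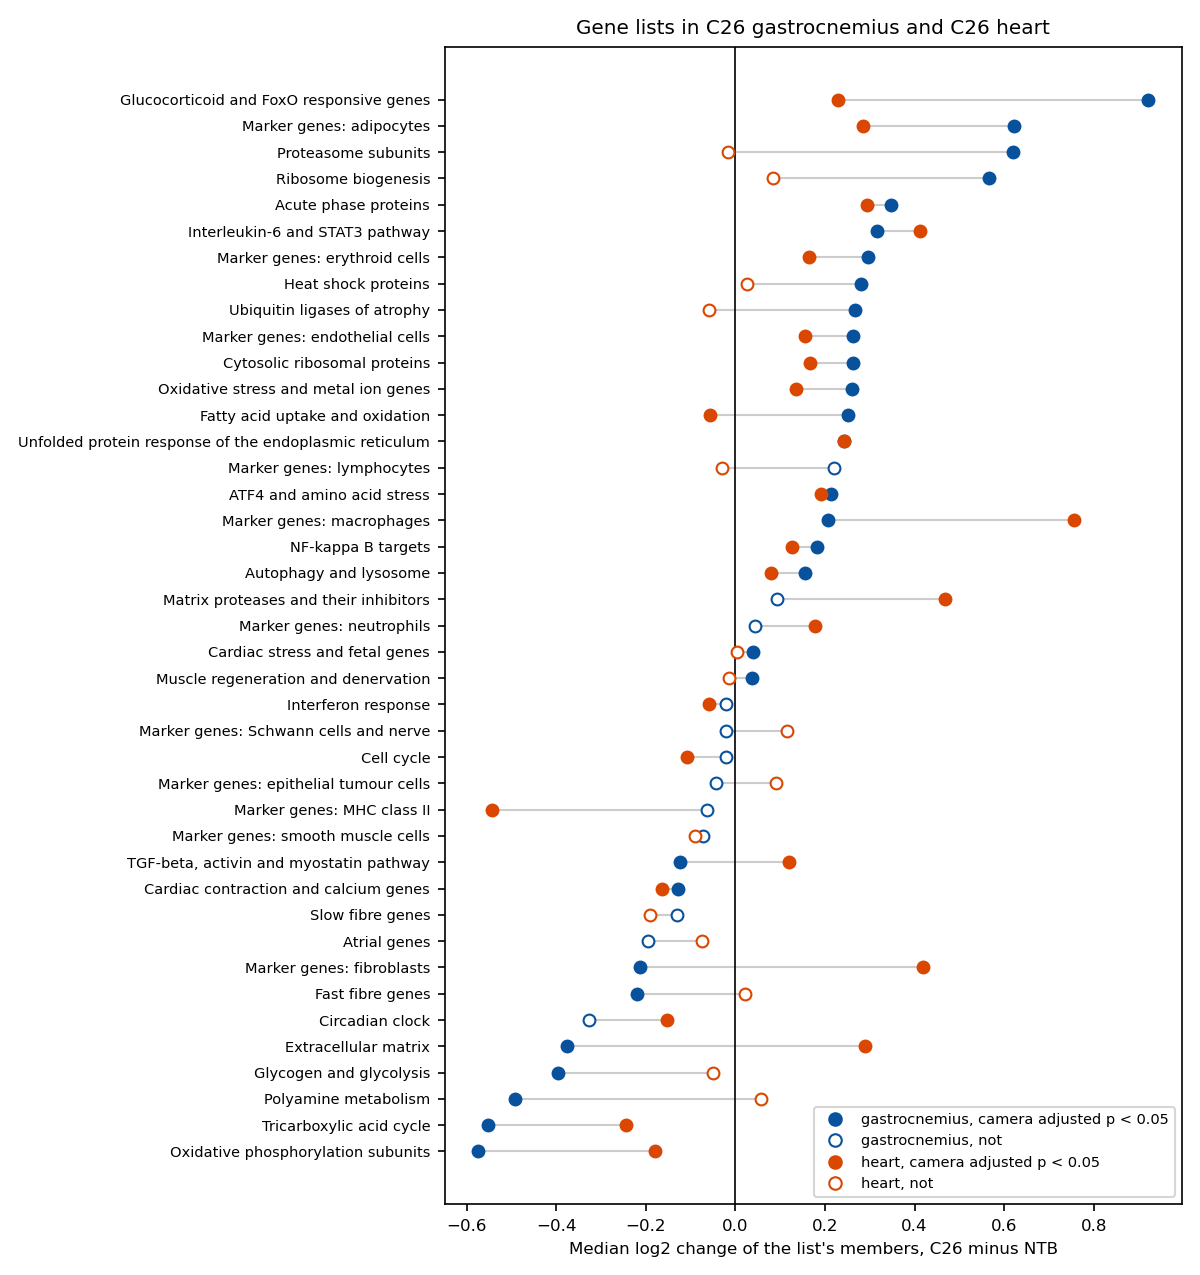
Median log2 change (C26 minus NTB, x axis) of each gene list in gastrocnemius (blue) and heart (orange), filled where camera's adjusted p was under 0.05. The proteasome median is 0.62 in gastrocnemius and -0.02 in heart, and the matrix median is -0.38 and 0.29.

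In all, 2282 genes were called in gastrocnemius, 54.0% of them up (47.4% with quantile normalization over all arrays), and 4153 had an unadjusted p under 0.05. At least 2-fold changes were found for 210 genes up and 233 down. For 3729 genes (19.3%) the 3 C26 and the 3 NTB arrays did not overlap, where chance gives 10%, and 2195 of these were called. C26 gastrocnemius array 3 lay apart from its group, and without it 3342 genes were called, 66.2% of them up. The lean towards rises depended on single arrays, with 47.0%, 45.7% and 47.2% up without C26 gastrocnemius arrays 1 and 2 and NTB gastrocnemius array 3.

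The acute phase list was called higher in C26 hearts. Lcn2 rose 21.5-fold (log2 4.43 ± 0.36, adjusted p = 5.03e-06), the secretoglobin Scgb3a1 11.9-fold (3.57 ± 0.20, adjusted p = 1.13e-07), Srpx 9.03-fold (3.17), Apod 7.67-fold (2.94 ± 0.13, adjusted p = 1.64e-08) and the cell cycle inhibitor Cdkn1a 7.49-fold (2.90). Prg4 (2.84), Vsig4 (2.55), complement C4b (2.52), fetuin A (Ahsg, 2.48 ± 0.15) and Cxcl13 (2.42 ± 0.52, adjusted p = 0.0166) completed the 10 largest rises, and Cxcl13 was not called without C26 heart array 3 or NTB heart array 1 or 2 (adjusted p up to 0.0943). Of 25 acute phase genes 12 rose and 0 fell (12 and 0 adjusted over the list alone), with Lrg1 at 2.33 and Lbp at 1.63, and 7 rose without C26 heart array 3 or NTB heart array 2 or 3. The median was 0.29 (adjusted p = 2.03e-12, adjusted p = 0.112 with an estimated correlation). Of 28 genes of the interleukin-6 and STAT3 pathway 11 rose and 0 fell (13 and 0 adjusted over the list alone), with Osmr at 1.66, Il4ra at 1.61, Il1r1 at 1.32, Socs3 at 1.07 (adjusted p = 0.0035) and Stat3 at 0.89. The median was 0.41 (adjusted p = 1.28e-16, adjusted p = 0.0510 with an estimated correlation). Of 29 NF-kappa B targets Selp (1.11), Icam1 (0.65), Ptgs2 (0.72) and Birc3 (0.48) rose (6 adjusted over the list alone). The median was 0.13 (adjusted p = 5.83e-04, adjusted p = 0.112 with an estimated correlation). Except for Selp these calls were lost without 1 or more arrays (adjusted p up to 0.246), and 1 was called without C26 heart array 3 and 2 without C26 heart array 1 or any 1 NTB heart array. In the interferon response Gbp6 (0.88), Ifi27l2a (0.77) and Oas2 (0.86) rose and Gbp3 (-0.93), Gbp7 (-0.86) and Gbp4 (-0.93) fell of 40 (3 and 7 adjusted over the list alone). The median was -0.06 (adjusted p = 0.0376, adjusted p = 0.655 with an estimated correlation), and -0.11 and -0.13 without C26 heart array 1 and NTB heart array 3. That list was not called without C26 heart array 2 or NTB heart array 1 or 2 (adjusted p up to 0.216). Oas2 was lost without NTB heart array 2 and Gbp4 and Gbp7 without C26 heart array 3 or NTB heart array 1 or 2 (adjusted p up to 0.0955), and 6 fell without C26 gastrocnemius array 3.

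The macrophage, matrix and matrix protease lists were called higher in C26 hearts. Of 20 macrophage markers 9 rose and 0 fell (17 and 0 adjusted over the list alone), with Lyve1 at 1.58, Cd68 at 0.98 and Ms4a7 at 0.96. The median was 0.76 (adjusted p = 1.28e-16, adjusted p = 0.130 with an estimated correlation). The count was 4 without any 1 of C26 heart arrays 1 to 3 or NTB heart arrays 2 and 3, and 14 without C26 gastrocnemius array 1. Of 50 matrix genes 7 rose and 0 fell (19 and 1 adjusted over the list alone), with Lox at 1.47, Vcan at 1.30 and Fbln1 at 1.09, and 11 and 12 rose without C26 gastrocnemius arrays 1 and 3. The median was 0.29 (adjusted p = 5.72e-11, adjusted p = 0.341 with an estimated correlation). Of 23 matrix proteases and inhibitors 9 rose and 1 fell (13 and 1 adjusted over the list alone), with Timp1 at 1.95, Mmp3 at 1.88 and Mmp2 at 1.33. The median was 0.47 (adjusted p = 1.20e-11, adjusted p = 0.112 with an estimated correlation). The fall of Mmp15 (-0.82) was lost without C26 heart array 1 or NTB heart array 1 or 3 (adjusted p up to 0.0666). Of 20 fibroblast markers Pi16 (1.30), Dpt (1.06) and Ly6a (0.88) rose (13 adjusted over the list alone). The median was 0.42 (adjusted p = 2.93e-09, adjusted p = 0.133 with an estimated correlation). Dpt and Ly6a were lost without NTB heart array 2 (adjusted p up to 0.113 for any 1 array), where 1 rose, and 6 and 5 rose without C26 gastrocnemius arrays 1 and 3. In the TGF-beta, activin and myostatin pathway Tgfbr2 (1.15) and Inhba (0.69) rose and Bmp4 (-0.83) fell of 34 (3 and 1 adjusted over the list alone), and the latter 2 were lost without C26 heart array 1 and others (adjusted p up to 0.199). The median was 0.12 (adjusted p = 0.0126, adjusted p = 0.478 with an estimated correlation). The neutrophil list was called higher, with Lcn2, Cxcr2 (0.78) and Mmp9 (0.64) called of 18 (6 adjusted over the list alone), 5 without C26 gastrocnemius array 3, and Mmp9 lost without C26 heart array 3 or NTB heart array 2 (adjusted p up to 0.0749). The median was 0.18 (adjusted p = 2.87e-04, adjusted p = 0.389 with an estimated correlation). The endothelial list was called higher, with Vwf (0.89), Lyve1 and Plvap (0.71) called of 20 (5 adjusted over the list alone), and Plvap lost without C26 heart array 3 or NTB heart array 2 (adjusted p up to 0.0899). The median was 0.15 (adjusted p = 0.0142, adjusted p = 0.478 with an estimated correlation). Adipocyte (median 0.28, and 0.17 without NTB heart array 3, adjusted p = 0.0065, adjusted p = 0.485 with an estimated correlation) and erythroid markers (0.16, adjusted p = 0.0393, adjusted p = 0.507 with an estimated correlation) were called higher, the latter not without C26 heart array 2 or 3 or NTB heart array 2 (adjusted p up to 0.558, median 0.06 and 0.09 without C26 heart array 3 and NTB heart array 2) and with 0 of 12 genes called by limma (0 adjusted over the list alone, and 2 at an unadjusted p under 0.05). MHC class II was called lower, with 0 of 10 genes called by limma (0 adjusted over the list alone, and 5 at an unadjusted p under 0.05), 4 without C26 gastrocnemius array 3 and 1 without C26 gastrocnemius array 1. The MHC class II list had a median of -0.54 (adjusted p = 0.0016, adjusted p = 0.435 with an estimated correlation). Not called were lymphocytes (-0.03, adjusted p = 0.649), Schwann cells and nerve (0.12, 0.263), smooth muscle (-0.09, 0.0596) and epithelial tumour cells (0.09, 0.195), with 0 lymphocyte and 0 Schwann cell genes called (0 adjusted over the list alone). The smooth muscle list was called lower without NTB heart array 3, C26 gastrocnemius array 1 or NTB gastrocnemius array 3 (adjusted p = 0.0204, 0.0451 and 0.0487). The single calls in the adipocyte, smooth muscle and epithelial lists, Agt (0.62), Smtn (-0.64) and Muc1 (0.52), (2, 1 and 1 adjusted over the list alone) were lost without C26 heart array 3 and others (adjusted p up to 0.252), and 3 adipocyte markers rose without C26 gastrocnemius array 3.

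The cardiac contraction and calcium list was called lower in C26 hearts. Trim63 (-0.07, adjusted p = 0.955), Fbxo32 (-0.13, 0.843) and Foxo1 (0.19) were not called, nor were Myh6 (-0.15), Myh7 (0.66, 0.268), Nppa (-0.53, 0.179), Nppb (-0.01), Myh1, Myh2, Myh4 and Mstn (-0.02). Acta1 fell by 0.54 ± 0.10 (adjusted p = 0.0083), a call lost without C26 heart array 2 or NTB heart array 1 (adjusted p up to 0.0621). The growth factor Fgf16 (-2.05 ± 0.15, adjusted p = 1.08e-06), Lgi1 (-1.94), the myosin light chain kinase Mylk4 (-1.87), the apelin receptor Aplnr (-1.60), Aqp6 (-1.58), B3galt2 (-1.53), Nrep (-1.44), the relaxin receptor Rxfp1 (-1.42), Scgb1c1 (-1.40) and Itgb6 (-1.30) fell most. Of 33 cardiac contraction and calcium genes Kcnip2 (-1.20), Hcn4 (-0.60), Camk2d (-0.62), Hrc (-0.66) and Mybpc3 (-0.55) fell (5 down and 1 up adjusted over the list alone). The median was -0.16 (adjusted p = 2.36e-04, adjusted p = 0.133 with an estimated correlation), and -0.10 without C26 heart array 1. Camk2d, Hrc and Mybpc3 were lost without C26 heart array 1 and others (adjusted p up to 0.240), with 2 called without C26 heart array 1 or NTB heart array 3 and 3 without C26 heart array 2 or NTB heart array 1 or 2. Proteasome subunits were not called as a list (median -0.02, adjusted p = 0.395), with 0 of 37 genes called by limma (0 adjusted over the list alone, and 2 at an unadjusted p under 0.05). Without C26 gastrocnemius array 1 or 3, 1 of them fell. Ubiquitin ligases of atrophy were not called (median -0.06, adjusted p = 0.564), with Asb2 (-0.90) and Fbxl22 (-0.73) down and Fbxo31 (0.59) and Cblb (0.66) up of 22 (2 and 3 adjusted over the list alone), the latter pair lost without most single heart arrays (adjusted p up to 0.127). The autophagy list was called higher, with Atg13 (1.03), Ctsl (0.79) and Bnip3 (0.83) called of 40 (5 adjusted over the list alone). The median was 0.08 (adjusted p = 0.0339, adjusted p = 0.712 with an estimated correlation). That list was not called without C26 heart array 3 or NTB heart array 1 (adjusted p up to 0.0941), Bnip3 was lost without any 1 heart array (adjusted p up to 0.180), and 6 rose without C26 gastrocnemius array 3. The glucocorticoid and FoxO list was called higher, with Cdkn1a, Mt1 (1.88), Mt2 (2.20), Fkbp5 (1.43) and Errfi1 (1.08) called of 30 (7 adjusted over the list alone). The median was 0.23 (adjusted p = 5.22e-06, adjusted p = 0.143 with an estimated correlation), and 0.14 and 0.15 without C26 heart array 1 and NTB heart array 2.

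Oxidative phosphorylation was called lower as a list in C26 hearts, while 0 of 76 genes were called by limma (0 adjusted over the list alone, and 8 at an unadjusted p under 0.05). The median was -0.18 (camera adjusted p = 1.37e-07, adjusted p = 0.507 with an estimated correlation). Without C26 gastrocnemius array 3, 1 fell. The tricarboxylic acid cycle was lower, with Suclg1 (-0.49) alone called of 26 (7 adjusted over the list alone), a call lost without any 1 heart array (adjusted p up to 0.174), and with 3 and 4 called without C26 gastrocnemius arrays 1 and 3. The median was -0.25 (adjusted p = 4.28e-09, adjusted p = 0.301 with an estimated correlation). Fatty acid genes were lower, but not without C26 heart array 2 or 3, NTB heart array 1 or NTB gastrocnemius array 2 (adjusted p up to 0.356), and Ucp2 (0.95) alone rose of 41 (1 adjusted over the list alone), a call lost without C26 heart array 1 and others (adjusted p up to 0.184). The median was -0.06 (adjusted p = 0.0421, adjusted p = 0.729 with an estimated correlation), and -0.22, -0.03, -0.10 and -0.11 without C26 heart array 1 and NTB heart arrays 1 to 3. Glycogen and glycolysis genes were not called (median -0.05, adjusted p = 0.283). Of 34, Eno3 (-0.62), Pgam2 (-0.69), Pfkm (-0.50) and Pkm (-0.43) fell and Phka1 (0.81) and Ppp1r3a (0.60) rose (6 and 4 adjusted over the list alone), and each was lost without NTB heart array 2 and others (adjusted p up to 0.199). The unfolded protein response was called higher, with Sdf2l1 (1.30), Dnajc3 (0.76), Edem1 (0.61), Manf (0.66) and Pdia4 (0.57) called of 29 (13 adjusted over the list alone). The median was 0.24 (adjusted p = 6.56e-10, adjusted p = 0.112 with an estimated correlation). Manf and Pdia4 were lost without C26 heart array 2 and others (adjusted p up to 0.197), 3 were called without C26 heart array 2 or 3 or any 1 NTB heart array, and 10 without C26 gastrocnemius array 3. ATF4 genes were called higher, with Slc3a2 (1.20), Atf3 (0.96), Slc7a5 (0.54) and Nupr1 (0.49) called of 34 (8 adjusted over the list alone). The median was 0.19 (adjusted p = 2.43e-06, adjusted p = 0.112 with an estimated correlation). Except for Slc3a2 these were lost without C26 heart array 2 and others (adjusted p up to 0.216), with 1 or 2 called without any 1 heart array and 7 without C26 gastrocnemius array 3. Oxidative stress and metal ion genes were called higher, with Mt1, Mt2, Gpx3 (0.84), Sod3 (0.75) and Hmox1 (0.77) up and Tfrc (-0.86) down of 26 (6 and 2 adjusted over the list alone), and Sod3 and Hmox1 were lost without C26 heart array 1 or NTB heart array 2 or 3 (adjusted p up to 0.1502), where 3 rose. The median was 0.14 (adjusted p = 0.0012, adjusted p = 0.437 with an estimated correlation).

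Of the other lists in C26 hearts, clock genes were called lower, with 6 of 19 down and 0 up (6 and 4 adjusted over the list alone), among them Hlf (-0.83), and only 1 fell without C26 heart array 2 or 3 or any 1 NTB heart array. The median was -0.15 (adjusted p = 0.0174, adjusted p = 0.389 with an estimated correlation), and -0.09 without C26 heart array 1 or NTB heart array 3. Up to 3 rose without 1 array (C26 gastrocnemius array 3). Cytosolic ribosomal protein genes were called higher, with Rpl3 (0.71) alone called of 52 (1 adjusted over the list alone), a call lost without C26 heart array 1 or 3 or NTB heart array 2 (adjusted p up to 0.111). The median was 0.17 (adjusted p = 4.11e-05, adjusted p = 0.389 with an estimated correlation). Cell cycle genes were called lower with Ccnd1 (-1.05) alone called of 30 (1 adjusted over the list alone), and not without C26 heart array 2 or NTB heart array 1 (adjusted p up to 0.0601). The median was -0.11 (adjusted p = 0.0133, adjusted p = 0.389 with an estimated correlation), and -0.06 and -0.07 without C26 heart array 2 and NTB heart array 3. Not called were ribosome biogenesis (median 0.08, adjusted p = 0.0625; Myc alone rose, by 1.30, 1 adjusted over the list alone; called without C26 heart array 1 or NTB heart array 2, 0.0250 and 0.0267), fast fibre genes (median 0.02, mean -0.09, 0.313), slow fibre genes (-0.19, 0.146), cardiac stress and fetal genes (median 0.00 and mean and test below 0, 0.811), atrial genes (-0.07, 0.599), muscle regeneration (median -0.01, mean 0.09, 0.861), polyamine genes (0.06, 0.514) and heat shock genes (median 0.03, mean -0.05, 0.389). From the fast fibre list on, 0, 1, 1, 1, 1, 1 and 0 genes rose and 3, 0, 1, 0, 1, 0 and 1 fell (2, 1, 2, 2, 2, 1 and 0 rose and 4, 0, 3, 3, 1, 0 and 1 fell adjusted over the list alone). In these, Casq1 (-1.18), Pgam2, Tpm1 (-0.42), Hdac9 (-0.52) and Hspb3 (-0.81) fell and Fhl1 (0.97), Clu (0.97) and Sat1 (0.87) rose. Pgam2, Tpm1, Hdac9, Hspb3 and Sat1 were lost without NTB heart array 3 and others (adjusted p up to 0.240).

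In all, 628 genes were called in heart, 65.9% of them up (51.9% of 2212 with the heart arrays alone and 55.1% of 2080 with array weights), and 2347 had an unadjusted p under 0.05. At least 2-fold changes were found for 141 genes up and 30 down. For 5335 genes (27.6%) the 3 C26 and the 3 NTB hearts did not overlap, where chance gives 10%, and all 628 called genes were among them. Without C26 heart arrays 1, 2 and 3 in turn the count was 397, 401 and 360, without NTB heart arrays 1, 2 and 3 it was 357, 328 and 364, and without C26 gastrocnemius array 3 it was 1147 (57.1% up).

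The tumour effect differed between the muscles for 756 genes. The effect in gastrocnemius minus that in heart was 2.60 ± 0.25 for Trim63 (adjusted p = 3.42e-05) and 2.45 ± 0.19 for Fbxo32 (adjusted p = 6.20e-06), and with Bex1 (2.83), Ankrd1 (2.55) and Csrp3 (2.12) these were the 5 largest differences towards gastrocnemius. The largest in the other direction were those of Ostn (-4.32 ± 0.34, adjusted p = 8.54e-06), Col1a1 (-3.16 ± 0.35), Pla2g7 (-3.14 ± 0.18, adjusted p = 2.47e-07), Plcd4 (-3.12 ± 0.32) and Mybph (-3.09 ± 0.28). Mt1 rose more in gastrocnemius (1.37, adjusted p = 5.82e-04), and Scgb3a1 (-2.48), Srpx (-2.98), Ahsg (-2.20) and Vsig4 (-2.27) rose more in heart. Of the lists 20 were called, 0 with an estimated correlation (adjusted p = 0.2496 to 0.6024), and 23 of 100 splits of the arrays gave as many. The effect was higher in gastrocnemius for the proteasome (median of the differences 0.66, adjusted p = 5.71e-20, 13 genes higher and 0 lower, 22 and 0 adjusted over the list alone, and so on in this order), ribosome biogenesis (0.51, 9.94e-13, 10 and 0, 20 and 0), fatty acid genes (0.40, 1.68e-07, 6 and 0, 10 and 1), ubiquitin ligases (0.27, 3.46e-06, 6 and 0, 10 and 0), glucocorticoid and FoxO responsive genes (0.51, 3.11e-06, 11 and 1, 12 and 4), heat shock genes (0.35, 3.11e-06, 4 and 0, 7 and 1), autophagy (0.17, 0.0011, 5 and 0, 10 and 0), cardiac stress genes (0.29, 0.0031, 5 and 2, 6 and 2), ribosomal proteins (0.11, 0.0107, 1 and 0, 0 and 0) and oxidative stress and metal ion genes (0.30, 0.0152, 5 and 1, 11 and 4). It was lower in gastrocnemius for the matrix (-0.61, 4.13e-24, 0 and 19, 0 and 28), fibroblast markers (-0.58, 5.75e-13, 0 and 8, 0 and 11), oxidative phosphorylation (-0.40, 1.35e-11, 0 and 2, 0 and 0), matrix proteases (-0.45, 3.69e-06, 0 and 4, 0 and 10), macrophage markers (-0.53, 2.39e-05, 0 and 1, 0 and 1), the TGF-beta pathway (-0.29, 4.09e-04, 1 and 5, 1 and 6), fast fibre genes (-0.28, 4.58e-04, 0 and 1, 0 and 7), the tricarboxylic acid cycle (-0.24, 4.58e-04, 0 and 2, 0 and 4), polyamine genes (-0.56, 0.0027, 0 and 2, 1 and 5) and glycolysis (-0.18, 0.0047, 2 and 6, 3 and 9).

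Some of these differences rested on single arrays. When C26 gastrocnemius array 3 was left out, the higher genes numbered 26 for the proteasome, 21 for ribosome biogenesis, 14 for fatty acid genes, 12 for autophagy, 10 for heat shock genes, 10 for metal ion genes and 2 for ribosomal proteins. The lower ones then numbered 5 for macrophage markers, 4 for oxidative phosphorylation, 3 for fast fibre genes and 3 for glucocorticoid genes. Lower genes without C26 gastrocnemius array 1 were 16 for oxidative phosphorylation, 10 for glycolysis, 6 for the tricarboxylic acid cycle, 5 for fast fibre genes and 4 for polyamine genes. Without C26 heart array 3, and without others, the higher genes numbered 6 for ribosome biogenesis, 3 for ubiquitin ligases, 2 for heat shock genes, 1 for metal ion genes and 0 for ribosomal proteins. The lower ones then numbered 5 for fibroblast markers, 1 for the tricarboxylic acid cycle and 0 for oxidative phosphorylation, fast fibre and glucocorticoid genes (2 for the TGF-beta pathway without C26 heart array 1 or 2 or NTB heart array 3). Without C26 gastrocnemius array 3 the tricarboxylic acid cycle (adjusted p = 0.0579) and glycolysis (0.0638) lists were not called, without C26 gastrocnemius array 2 the ribosomal protein list (0.220), and without C26 gastrocnemius array 1 or NTB gastrocnemius array 3 the metal ion list (up to 0.0904). When C26 gastrocnemius array 3 was left out, the median difference was -0.22 for oxidative phosphorylation, -0.12 for the tricarboxylic acid cycle, -0.10 for glycolysis, 0.36 for autophagy, 0.23 for ribosomal proteins and 0.46 for the metal ion list. Without C26 gastrocnemius array 1 it was 0.04 for autophagy, -0.40 for the tricarboxylic acid cycle, 0.18 for the metal ion list, 0.23 for heat shock genes and -0.29 for macrophage markers. It was 0.11 for autophagy and 0.06 for ribosomal proteins without C26 gastrocnemius array 2, 0.19 for the metal ion list without NTB gastrocnemius array 3 and 0.19 for cardiac stress genes without NTB heart array 3. The acute phase (median -0.10, adjusted p = 0.249) and neutrophil lists (-0.19, 0.0763) were not called, but were without C26 gastrocnemius array 3 (0.0105 and 0.0023), and neutrophils also without C26 heart array 3, NTB heart array 3 or NTB gastrocnemius array 2 (0.0384, 0.0264 and 0.0332). With the block the interleukin-6 and STAT3 pathway (-0.20, 0.0643) reached an adjusted p of 0.0448 and MHC class II (0.46, 0.0643) an adjusted p of 0.0396 (adjusted p = 0.334 and 0.652 with the block and an estimated correlation). The former was also called without C26 heart array 2, NTB heart array 3, C26 gastrocnemius array 2 or NTB gastrocnemius array 3 (0.0190 to 0.0341), and the latter without C26 heart array 1, NTB heart array 2, C26 gastrocnemius array 1 or 2 or NTB gastrocnemius array 2 (0.0022 to 0.0375). Not called with or without the block (adjusted p = 0.0790 to 0.972) were NF-kappa B targets, interferon response, slow fibre genes, cardiac contraction (median 0.02, mean -0.08), atrial genes, muscle regeneration (median -0.04, mean 0.19), ATF4 genes (median -0.03, mean 0.04), unfolded protein response, clock genes (median -0.04, mean 0.04), cell cycle and the markers of lymphocytes, erythroid, endothelial, adipocyte, Schwann, smooth muscle (median -0.03, test above 0) and epithelial tumour cells. Of these, atrial genes were called without NTB heart array 3 (0.0498), lymphocytes without NTB heart array 2 or C26 gastrocnemius array 1 or 2 (0.0042 to 0.0396), erythroid markers without C26 heart array 3, NTB heart array 2 or C26 gastrocnemius array 1 (0.0048 to 0.0398), endothelial markers without NTB gastrocnemius array 2 (0.0237) and adipocyte markers without C26 gastrocnemius array 1 (0.0172). In the lists not called up to 4 genes were higher in gastrocnemius and up to 4 lower (4 and 7 adjusted over the list alone). Of 19 clock genes 3 differed towards gastrocnemius, Rora (1.22) and Arntl (1.29) among them, and 1, Dbp (-1.84), towards heart, 2 without NTB heart array 2. Of the 756 genes, 374 had the higher effect in gastrocnemius and 382 in heart, 556 were called in gastrocnemius alone, 116 in heart alone, 51 in both and 33 in neither, and 2802 had an unadjusted p under 0.05. The count was 1357 with the block and 1600 without C26 gastrocnemius array 3, when 63.5% had the higher effect in gastrocnemius (61.7% of 2433 with array weights). It was 490, 476, 477, 458 and 479 without C26 heart arrays 1 and 3 and NTB heart arrays 1, 2 and 3.

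Genes that rose in both muscles included Lcn2, Mt1 and Mt2, with Cdkn1a (2.17 in gastrocnemius and 2.90 in heart), Apod (2.02 and 2.94), C4b (1.80 and 2.52), Lrg1 (1.77 and 2.33), Lbp (1.63 and 1.63) and Fkbp5 (1.44 and 1.43). Mylk4 (-2.21 and -1.87), Nrep (-3.03 and -1.44), Itgb6 (-2.80 and -1.30) and Casq1 (-2.40 and -1.18) fell in both. In all 147 genes rose in both, where independent lists would share 26.4, and 69 fell in both, where they would share 11.6. The 216 genes changed in both muscles in the same direction were 366 with the block and 395 without C26 gastrocnemius array 3, and 141, 132, 124, 127, 115 and 127 without C26 heart arrays 1 to 3 and NTB heart arrays 1 to 3. Across all genes the effects correlated with r = 0.322 (rho = 0.246), and 57.1% had the same sign. Across the 2669 genes called in either muscle r was 0.403 (rho = 0.439, 73.5% with the same sign), and genes are not independent replicates.

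Opposite calls in the muscles were found for 25 genes, all chosen after their values were seen and for being called in both muscles, so that a test of their difference adds nothing. The lipase Pla2g7 fell by 1.49 in gastrocnemius and rose by 1.64 in heart, and the phosphatase Alpl fell by 1.04 and rose by 0.99. For 18 genes the fall was in gastrocnemius, where independent lists would share 22.5, and for 7 it was in heart, where they would share 13.7. Here too the calls were not independent. Some of these calls rested on single arrays, as that of Dpt in heart (1.06), lost without NTB heart array 2 (adjusted p = 0.0501).

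**Figure D3:**
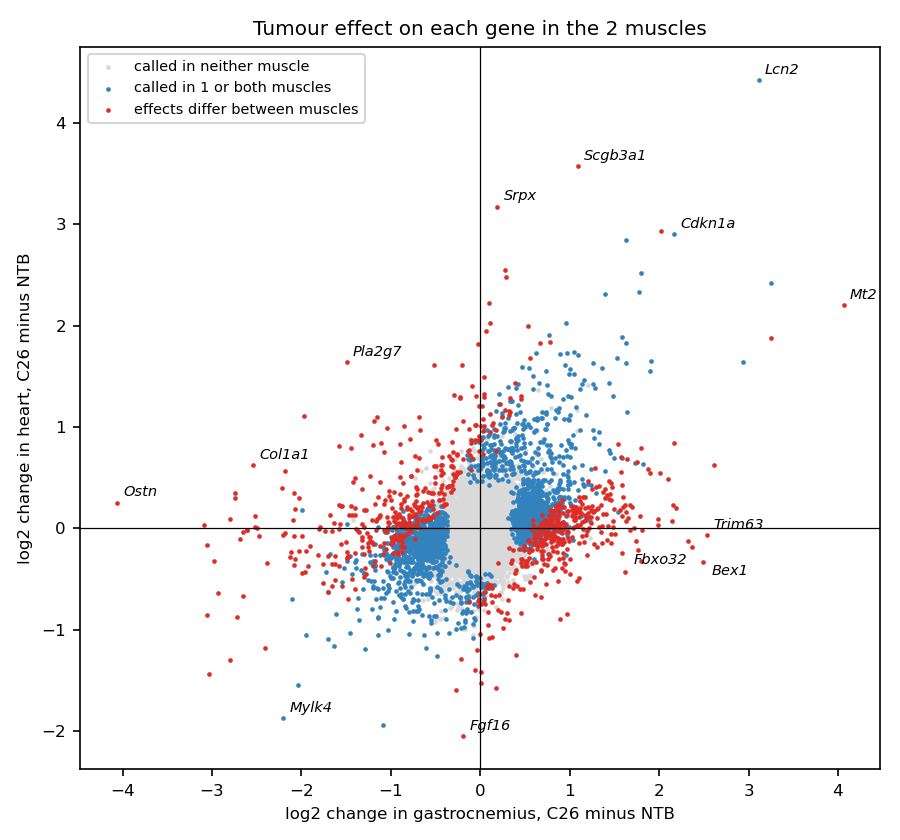
Log2 change (C26 minus NTB) of each gene in gastrocnemius (x axis) and heart (y axis). Blue marks genes called in 1 or both muscles, and red, which overrides blue, the 756 genes whose effects differ between the muscles.

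In NTB mice the muscles differed in the genes that define them. Heart was higher for the cardiac troponin Tnni3 (7.66 ± 0.14, 202-fold), Tecrl (7.23), phospholamban (Pln, 7.07), Nppa (6.63) and Ankrd1 (6.61), and for the heart myosin Myh6 (5.76). Gastrocnemius was higher for parvalbumin (Pvalb, -8.64 ± 0.21 as heart minus gastrocnemius), Tnnc2 (-8.13), Myh4 (-8.08), the calcium pump Atp2a1 (-7.68) and Ampd1 (-7.59). In all 4787 genes were higher in heart and 3047 in gastrocnemius, together 40.53%.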

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

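The tests of tendon markers, adipose markers outside the gene lists, macrophage markers and abundant liver transcripts were chosen only after the result was seen, and the bounds of the basement membrane and ribosomal protein tests were made stricter after their values were seen.

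The tumour effect differed between the muscles for 756 genes by a test of the difference itself (gastrocnemius minus heart, log2), and 25 genes were called in opposite directions. That count was 458 to 512 without any 1 heart array, and 1600 without C26 gastrocnemius array 3. The effect was higher in gastrocnemius for Bex1 (2.83), Trim63 (2.60), Ankrd1 (2.55), Fbxo32 (2.45) and Csrp3 (2.12). It was lower there for Ostn (-4.32), Col1a1 (-3.16), Pla2g7 (-3.14), Plcd4 (-3.12) and Mybph (-3.09). The cohorts of the muscles were separate, so muscle and cohort cannot be told apart.

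The gene lists that differed higher in gastrocnemius had median differences of 0.27 for ubiquitin ligases, 0.66 for the proteasome, 0.17 for autophagy, 0.51 for glucocorticoid and FoxO genes, 0.29 for cardiac stress genes and 0.40 for fatty acid genes. The others on that side were ribosome biogenesis (0.51), ribosomal proteins (0.11), oxidative stress and metal ion genes (0.30) and heat shock genes (0.35). On the lower side were the TGF-beta pathway (-0.29), the extracellular matrix (-0.61), matrix proteases (-0.45), fast fibre genes (-0.28), oxidative phosphorylation (-0.40, and -0.22 without C26 gastrocnemius array 3) and the tricarboxylic acid cycle (-0.24). Glycolysis (-0.18), polyamine genes (-0.56), macrophage markers (-0.53) and fibroblast markers (-0.58) were lower too. With an estimated correlation camera called 0 of these lists, the lowest adjusted p being 0.2496, and 5 lists had an unadjusted p under 0.05.

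Splits of the C26 and NTB labels within each muscle test against no tumour effect, not against equal effects in both. For the 756 genes 2 of 100 such splits (drawn from 200) gave as many, the real one included. The highest other split gave 2171 genes and exchanged the labels of all hearts, so that the tumour effects added up. These splits also exchange gastrocnemius arrays across the pairs of the same number. Of the 80 splits that part all these pairs, 2 gave as many genes (2171 and then 690 in the others), and 2 of 80 did so with the pairs as a block (1812 in the real split). For genes changed in both muscles in the same direction 1 of 100 splits was as large (216 against 25 at most), and 1 of the 80. That count was 115 to 141 without any 1 heart array, and 395 without C26 gastrocnemius array 3. For the number of lists that differed chance cannot be excluded (20 against 29 at most, 23 of 100 splits as large).

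Each comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05, and in each of them only 1 split, the real one, gave as large a value. In gastrocnemius 2282 genes were called against 178 at most in the other splits, and 29 lists against 19. In heart 628 genes were called against 0, and 26 lists against 18. Between the muscles of NTB mice 7834 genes were called against 0.

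The matrix list was called lower in C26 gastrocnemius (median -0.38, adjusted p = 0.262 with an estimated correlation), led by Col1a1 (-2.54). Basement membrane genes, around every fibre, would keep their level if less tendon were the whole cause. Their median was -0.19 (SE 0.10), between the bounds as tightened after it was seen, so it does not decide. Of 14, 4 fell (Nid2 by 0.69 and Col15a1 by 0.65, the others lost without 1 or more arrays). Less tendon stays open, as the 5 tendon markers that are not matrix genes were between the bounds too (median -0.38, SE 0.56). Of all 14 tendon markers 8 fell and 0 rose (median -0.57), led by Tnmd (-2.66), Kera (-2.61) and Chad (-2.38). Fewer fibroblasts stay open as well, since fibroblast markers that are not matrix genes lay between the bounds (median -0.13, SE 0.10). Lower matrix expression in the muscle of tumour-bearing mice, the biological explanation, was not tested apart from these.

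C26 gastrocnemius array 3 lay apart from its group, with oxidative phosphorylation genes at -0.58, adipocyte markers at 0.82 and macrophage markers at 0.46 (SE 0.09) against the other arrays of the group. Of 17 adipose markers outside the gene lists 13 were highest there (median deviation 0.30, SE 0.17), so adipose tissue stays open. Some led narrowly, as Fasn (8.30, and 8.20 in NTB gastrocnemius array 3), and Aqp7 stood at -0.54. By the slope of deviations on brightness (-0.129) a compressed signal would give macrophage markers -0.11, opposite in sign to 0.46, in 1 array. It stays open for the lower lists. Ribosomal protein genes deviated by -0.27 (SE 0.05), at the bound set, and proteasome genes by -0.41 (by the slope -0.53 and -0.42). Without this array the adipocyte list was not called in gastrocnemius (adjusted p = 0.421, range over the alternatives 5.39e-05 to 0.627). No biological explanation was tested, as no label sets it apart.

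Scgb3a1, an airway secretoglobin, and Ahsg, a liver protein, rose in C26 hearts by 3.57 and 2.48. Airway or lung tissue in the C26 hearts is excluded by the lung and airway markers, whose median change was 0.07 (SE 0.06). Liver tissue in the C26 hearts is excluded by the most abundant liver transcripts, since the largest change of Alb, Apoa1, Apoa2 and Ttr was 0.25 and Alb (a mean of 5.05 in C26 hearts) changed by -0.20. The liver test set first, the median of 12 liver markers (0.22, SE 0.18), did not decide it, and Trf (1.07) and Rbp4 (0.69) rose. A rise of both genes within heart tissue of tumour-bearing mice stays a hypothesis, found and tested on the same arrays.

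Outside the comparisons, array features without a gene name were tested in the same way. Of 13800 such features 107 changed in gastrocnemius (72 higher and 35 lower in C26) and 2 in heart.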

How the results depend on the processing

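Only the alternative without both gastrocnemius arrays numbered 3 was chosen after seeing the data. No named gene that passed its test in either setting changed direction under an alternative that was run, nor did the test of a gene list. The median of the cardiac stress list in gastrocnemius, 0.04, was -0.04 without NTB gastrocnemius array 3 (adjusted p = 0.0294) and just below 0 without both gastrocnemius arrays numbered 3. Among all genes 3 of the 7704 called in both settings between the muscles of NTB mice changed direction with the mean of all transcripts of a gene. Over the named genes 16691 values kept their side of the threshold, 412 came to pass it and 1080 no longer passed it, and over the gene lists these were 2701, 55 and 155. Genes changed in gastrocnemius numbered 2282, 4234 with array weights, 894 with the arrays of the compared groups alone and 1748 to 3342 without 1 array. With the compared groups alone heart had more calls than gastrocnemius, the reverse of the other settings. Genes changed in heart numbered 628, 355 with no moderation, 2080 with array weights, 2212 with the compared groups alone, 1012 with the block, 1374 without both gastrocnemius arrays numbered 3 and 328 to 1147 without 1 array. The highest of these was without C26 gastrocnemius array 3, and each heart array left out gave 328 to 401. Genes with a different tumour effect numbered 756, 471 with no moderation, 2433 with array weights, 1357 with the block, 1612 without both arrays numbered 3 and 458 to 1600 without 1 array. Genes changed in both muscles in the same direction numbered 216, then 123, 734, 366 and 409 in these settings and 115 to 395 without 1 array. Genes different between the muscles of NTB mice numbered 7834, and 6675 to 9038 without 1 array. Leaving out a gastrocnemius array moves heart counts only through the variance per gene that all arrays share. Otherwise the cause was not tested, beyond fewer degrees of freedom with 1 array fewer and the lowest array weight of C26 gastrocnemius array 3. Of 29, 26 and 20 lists called in gastrocnemius, in heart and for the difference, camera with an estimated correlation called 0, 0 and 0 (8, 10 and 5 at an unadjusted p under 0.05) and fry 26, 10 and 8. Without 1 array the lists called were 27 to 31, 22 to 27 and 20 to 23. The block called 3145 genes in gastrocnemius and 29, 27 and 22 lists. It added 3 list calls, smooth muscle markers in heart (adjusted p = 0.0463, range over the alternatives 0.0204 to 0.507) and, for the difference, the interleukin-6 pathway and MHC class II, and 49 calls of named genes, and it ended none. With an estimated correlation the block called 1 list, the interleukin-6 pathway in heart (adjusted p = 0.0267), and 0 in gastrocnemius and for the difference. In heart the arrays of the same number did not deviate together, so a block has no ground there. The comparison of NTB muscles could not be fitted with the block. The alternative with the other deposited table was not run, because its columns were not matched to samples by name. The correlation of the tumour effects was 0.271 to 0.356 over the alternatives. No scaling moved the share of genes that rose by more than 10 points or the median of all genes by more than 0.1.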

Other observations

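These genes were chosen after their values were seen, and no list of them was fixed or tested. In C26 gastrocnemius Jph2 (junctophilin 2) fell by 2.02, Sypl2 (mitsugumin 29) by 2.61 and Stac3 (a partner of the calcium channel) by 1.64. The chloride channel Clcn1 (-1.49), the sodium pump subunit Atp1b2 (-1.93), the water channel Aqp4 (-2.48) and the potassium channel subunit Kcng4 (-2.08) fell too, as did Prkag3 (-2.69), a subunit of AMP kinase, and the transcription factor Mef2c (-2.09). In each of these 9 genes all 3 C26 arrays lay below all 3 NTB arrays. None of these 9 was called in heart, and the effect differed between the muscles in each of them, in Clcn1 not without NTB heart array 1 (adjusted p = 0.0546).

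In C26 hearts, in genes chosen in the same way, the alarmin Il33 rose by 2.22 and the chemokines Ccl6, Cxcl14, Ccl9 and Ccl8 by 2.32, 1.73, 1.72 and 1.23. The effect differed from gastrocnemius for Il33 (adjusted p = 0.0011, -2.12) and Ccl8 (adjusted p = 0.0083, -1.01), not for the others. As these genes were chosen for their values, that test adds no support.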
